A study of Mus musculus with 4 samples.

How the data were processed

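RNA was sequenced from 4T1 cells in 4 samples, 2 that received EGFP mRNA (Mock) and 2 that received uniSTING mRNA. Per the labels' protocols, total RNA was extracted from the treated cells with a column kit and libraries were made with the NEBNext Ultra RNA kit; a strand-marking step, poly(A) selection or rRNA depletion is not given in the sources used here. The deposited values were raw counts per gene, 1 table per sample. Per the file headers, the counts were made with featureCounts 2.0.1 over exons grouped by gene, in paired-end mode and without a strand option, on the Ensembl 103 annotation of GRCm39 and on alignments of uniquely mapped reads. Per the submitters' processing notes, the aligner was HISAT2, whose version is not given in the sources used here. Counting without strand means that reads of overlapping or antisense genes cannot be told apart, and unique mapping means that near-identical copies (histone genes, ribosomal protein pseudogenes, H2 genes) lose reads.

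The tables listed 53647 genes, of which 32115 had no read in any sample. Gene identifiers were given symbols from an identifier table, which matched 52093 of them, and 3 older symbols were replaced by current ones (Sting1, Ero1a, H2-Ea). Coordinates are those of the deposited tables (GRCm39). GC content was taken from reference transcripts of an older annotation by gene identifier and covered 99.9% of the tested genes. The delivered EGFP and uniSTING sequences are not part of the mouse annotation, so delivery was not checked here.

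Groups and replicate numbers were taken from the sample titles. The 2 libraries of each group were compared before use, by the variance between 2 libraries (a robust estimate over genes from the median absolute deviation) divided by the variance that counting alone gives. On simulated counts this ratio was 1.06 for repeat runs of 1 library and 91.9 for libraries with an added coefficient of variation of 10%, for genes over 10000 counts.

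Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter by group (minimum count 10, minimum total count 15), glmQLFit and glmQLFTest on the group, and Benjamini-Hochberg adjustment over all 12972 genes tested, at a threshold of 0.05. The common coefficient of variation, which edgeR calls biological, was 3.15%. It was estimated from the libraries of each group, whose spread may be technical. The standard error of a log2 fold change was derived from the quasi-likelihood F statistic and is approximate. CPM values are counts divided by the TMM-scaled library size, given as mean ± SD. Fold changes of 1 replicate number are differences of log2 CPM with a prior count of 2. For genes with few counts, the ratio of summed counts is given with an exact 95% binomial interval, and a count of 0 was set at a floor of 3 counts over the group.

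Gene lists were tested with camera (limma 3.58.1) on log2 CPM, at a preset inter-gene correlation of 0.01 and with an estimated one, over 25 of 28 lists that had at least 3 tested genes. With fry, 17 lists moved on balance in 1 direction and 22 held changed genes in either direction, at an adjusted p under 0.05. Past fry in 1 direction but not past camera at the preset correlation were the NF-kB, chemokine, checkpoint, p53, stress response and epithelial lists, all upward. The G1/S list did the same downward. The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names a panel of 20 genes, the 8 genes with the largest rise and the 8 with the largest fall (adjusted p under 0.05, mean CPM of at least 1, both libraries of one group above both of the other, no predicted or clone names), and up to 4 genes with the smallest p from each list; genes named in the text are a part of these, unless said otherwise. Some of the genes the rule names, a panel gene among them, are not reported here.

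The alternatives were DESeq2's size factors in edgeR, no filter, a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, and a fold threshold of 2. Chosen after seeing the data were the removal of the trend of each library's counts with gene length, or with length and GC content (lowess with a span of 0.3, entered as offsets), leaving out 54 genes seen only in replicate 1 (at least 20 counts in a replicate 1 library and replicate 2 counts at most 5% of replicate 1 counts), and each replicate number alone.

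The tests were checked on simulated counts for 12972 genes with the means, library sizes and dispersion of these samples and 200 changed genes. In the simulated comparison of uniSTING with Mock, 40.8% of genes changed 1.25-fold, 67.3% of those changed 1.5-fold, 93.8% of those changed 2-fold and 95.8% of those changed 4-fold were recovered, with 6 false calls among 150. The dispersion came from the libraries of a group, whose spread may be technical. Far more genes passed in the data than were changed in the simulation. These rates therefore do not give the sensitivity or error rate for an effect between separate cultures. A list of genes shifted together was found at the preset correlation and none of 24 unshifted lists was called, whereas the estimated correlation missed the shifted list too. Here the genes were drawn independently and none outside the shifted list was changed. The check therefore does not cover lists whose genes vary together. A simulated length trend (rho -0.70) was reduced to -0.01 by the removal step. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.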

Results

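Gene expression was measured by RNA sequencing in 4T1 cells, a mouse mammary carcinoma line of BALB/c origin, after delivery of mRNA. One group received mRNA for uniSTING, an engineered mimic of the innate immune adaptor STING, and the Mock group received mRNA for the fluorescent protein EGFP. Each group held 2 libraries, which the labels number as preparations and which are called replicates 1 and 2 here. Total counts were 17502694 and 22039546 in the Mock libraries and 18843543 and 25071840 in the uniSTING libraries. Between 17604 and 18478 genes had a count in a library. The most abundant gene, the translation elongation factor Eef1a1 (outside the rule for named genes), took 1.86% of the counts in each Mock library and 2.08% in each uniSTING library. The labels name a transfection reagent and lipid nanoparticles as carriers without saying which was used for which library, and they give neither dose nor time.

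The comparison of uniSTING with Mock addressed how the mimic affects type I interferon signalling and which other pathways respond in the tumour cells. Of 63 tested interferon-stimulated effector genes, 50 rose and 1 fell, with a median log2 fold change of 0.72. Ifit1, which binds viral RNA, rose from 2.71 ± 0.575 to 12.4 ± 0.182 CPM (SD, n = 2 libraries per group), and the chemokine Cxcl10 rose from 1.29 ± 0.347 to 6.64 ± 0.125 CPM. Lists of glycolysis and hypoxia, cholesterol synthesis and ribosomal protein genes rose as well, with medians of 0.49, 0.48 and 0.31. The list tests of all of these were lost with an estimated correlation (limma's camera, adjusted p from 0.283 to 0.351). Once a trend of fold changes with gene length was removed, the ribosomal protein median was 0.16. The glycolysis and cholesterol medians were then 0.50 and 0.50. Replication-dependent histone genes, fibronectin (Fn1), the matrix protease Mmp9 and the proliferation marker Mki67 were lower in uniSTING. The adaptor gene itself, Sting1, did not pass the test, at 19.6 ± 0.203 CPM in Mock and 20.9 ± 1.25 CPM in uniSTING.

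Of 12972 genes tested, 6515 (50.2%) passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 3225 of them higher and 3290 lower in uniSTING. Most of these changes were small, with a median absolute log2 fold change of 0.33 and 3140 genes (48.2%) under 1.25-fold. As similar numbers of genes rose and fell, a list whose genes go both ways resembles the tested genes at large in that respect, though its median can differ. At least 2-fold changes were found for 414 genes, 259 higher and 155 lower. Among the 414 genes, 336 reached 2-fold in the replicate 1 libraries alone and 349 in the replicate 2 libraries alone. These single-replicate fold changes use a prior count of 2, which shrinks those of low-count genes, and so differ in measure from the fitted ones. All 414 had the same direction in both replicate numbers. The 2-fold counts moved by over 1.5 times in some settings, to 172 higher and 95 lower with DESeq2, to 257 lower without the low count filter, to 102 lower without Mock replicate 1 and to 241 lower without uniSTING replicate 1.

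**Figure D1:**
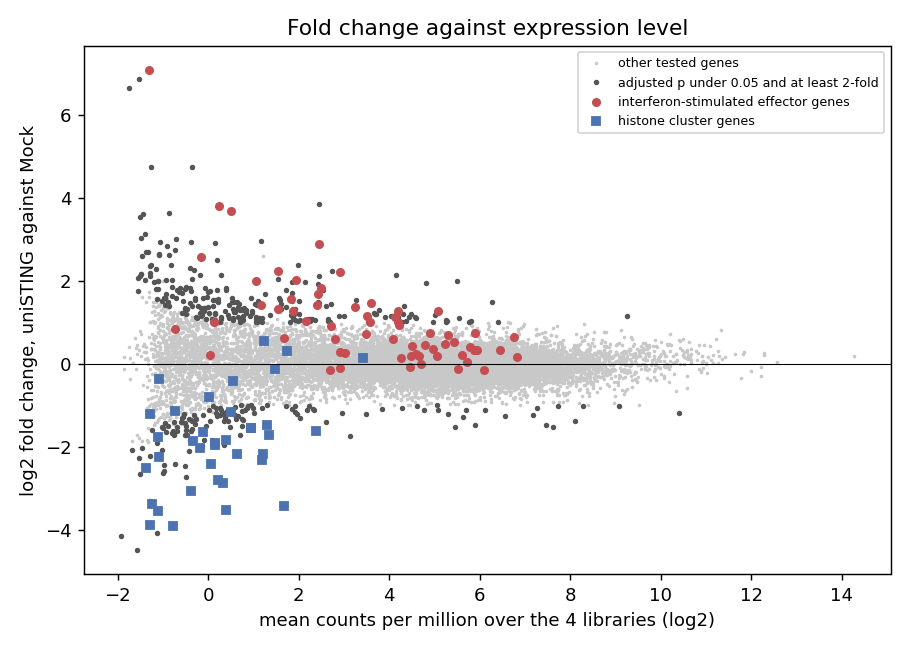
Log2 fold change of uniSTING against Mock (vertical axis) for 12972 tested genes against the mean CPM over the 4 libraries (horizontal axis, log2), with 63 interferon-stimulated effector genes in red and 37 histone cluster genes in blue. Fold changes of at least 2-fold at an adjusted p under 0.05 (dark points, 414 genes including coloured ones) lay mostly at low expression, and the topmost red point is Oas2, which had no count in Mock and whose fitted value depends on the prior count.

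The 2 libraries of a group differed little. Over genes with at least 50 counts, the variance between them was 1.31 to 1.80 times that of counting noise, without growth at high counts of the size seen between libraries of different groups, where it reached 170 to 182 times for genes with at least 10000 counts. They were kept as 2 libraries per group, as the labels number them. A spread above counting noise does not show that they are independent, since a repeat preparation of 1 RNA sample would also exceed counting noise. The labels do not say that the preparations came from separate cultures, so p-values here measure only the spread between these libraries, which may be technical, and compare the libraries rather than the conditions.

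**Figure D2:**
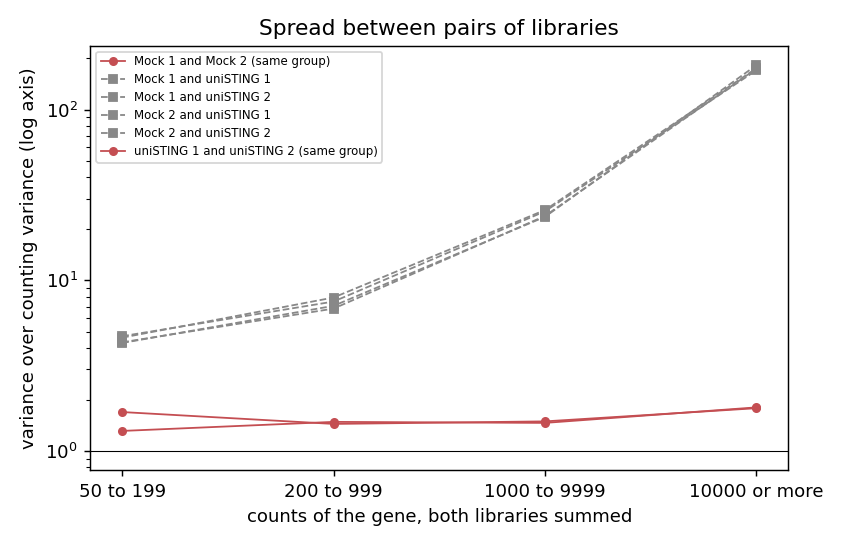
Variance between 2 libraries divided by the counting variance (vertical axis, log scale) for genes grouped by their counts summed over both libraries (horizontal axis), for each of the 6 pairs of libraries. Pairs of the same group (red) stay between 1.31 and 1.80, and pairs of different groups (grey) rise to between 170 and 182.

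Among interferon-stimulated effector genes, the products of which restrict virus replication, 26 of the 50 that rose did so by at least 2-fold. The median log2 fold change of the 63 tested genes was 0.72, with 0.81 in the replicate 1 libraries and 0.66 in the replicate 2 libraries. Isg15, a ubiquitin-like modifier (ENSMUSG00000035692, chromosome 4, 156283912 to 156285253, GRCm39), rose from 10.8 ± 0.810 to 26.1 ± 0.568 CPM, a log2 fold change of 1.27 (SE 0.08, adjusted p = 3.29e-07). Ifit1 (ENSMUSG00000034459, chromosome 19, 34618271 to 34627409) rose by 2.21 (SE 0.15, adjusted p = 5.32e-07) and Ifi44 by 2.89 (SE 0.16, adjusted p = 1.46e-07). The membrane protein gene Ifitm3, the most abundant of these examples, rose 1.55-fold to 132 ± 3.66 CPM. Genes near the floor in Mock rose too, with 3 and 3 counts of Ifit3b in Mock and 44 and 51 in uniSTING, a ratio of 14.3 (95% counting interval 6.31 to 39.8), and 8 against 115 counts of Mx2 in all, a ratio of 12.9 (6.35 to 30.7). Mx1, with 1 count in Mock and 27 in uniSTING, had a ratio of 24.3 (4.01 to 995) and was too low to be tested. Oas2, singled out after its values were seen, had no count in Mock and 35 in uniSTING, at least 10.6-fold higher against a floor of 3 counts over the group. Oas3, another 2'-5'-oligoadenylate synthetase gene, rose by 2.23 on the log2 scale (SE 0.26).

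The interferon-stimulated list stood apart from the other genes in camera's test at a preset correlation of 0.01 (adjusted p = 6.57e-12 over 25 lists), with 53 genes rising and 2 falling adjusted over the list alone. Its call was lost with an inter-gene correlation estimated from these 4 libraries (adjusted p = 0.283), as were those of all 10 lists past the preset test. That setting also rests on the spread of 4 libraries only. Over the 10 lists the estimates ran from -0.043 (mesenchymal transition) to 0.531 (mitochondrially encoded genes). For the interferon-stimulated list the estimate was -0.011, below the preset value, so its lost call does not show correlation among its genes. With Oas2 set at its lower bound, which lies above the list's median, the median is 0.72 by construction. Intervals and floors cover counting error only.

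**Figure D3:**
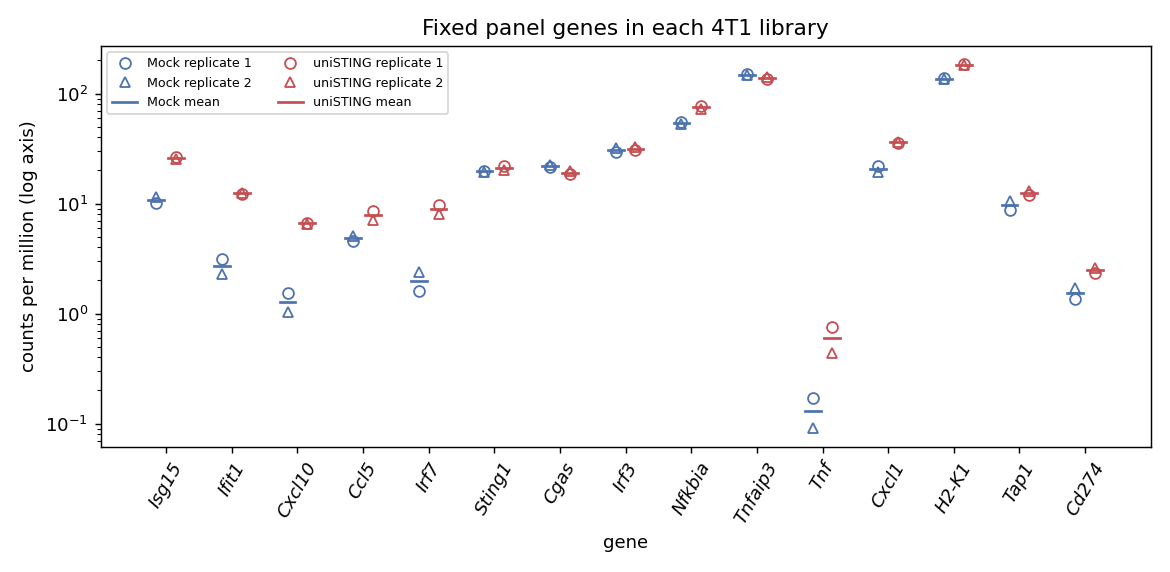
CPM (vertical axis, log scale) of 15 of the 16 panel genes with a count in every library, with an open symbol for each library and a bar for each group mean. Isg15, Ifit1, Cxcl10 and Irf7 lie apart between Mock (blue) and uniSTING (red), whereas the libraries of the groups overlap for Irf3 and lie close together for Sting1, neither of which passed the test.

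Transcripts of the interferons themselves were scarce. Of 20 type I and III interferon genes, 3 had a count in any library, with 8 counts over the Mock libraries and 33 over the uniSTING libraries. Ifnb1 had 3 and 0 counts in Mock and 4 and 8 in uniSTING, a ratio of 3.60 whose 95% interval (0.972 to 19.9) includes no difference. Ifnz, singled out after its values were seen, had 3 and 2 against 9 and 10 counts. Ifnl3 had no count in any library, which allows up to 0.0759 CPM in Mock and 0.0683 CPM in uniSTING, so that a difference was not detectable at this depth.

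Among 28 tested genes for nucleic acid sensing and interferon signalling, 10 rose, 5 fell and 13 did not pass (10 and 5 adjusted over the list alone), and the list did not pass its test (median 0.10, adjusted p = 0.174). The transcription factor genes Irf7 and Irf9 rose, Irf7 from 1.99 ± 0.573 to 8.85 ± 1.22 CPM (log2 fold change 2.12, SE 0.20) and Irf9 by 1.13 (SE 0.09). Ddx58, which encodes the RNA sensor RIG-I, rose 1.45-fold. Cgas, the cytosolic DNA sensor, fell by 0.21 (SE 0.07, adjusted p = 0.0367) and the kinase gene Jak1 by 0.26. The call of Cgas was lost with DESeq2 (adjusted p = 0.239) and without Mock replicate 2 or either uniSTING replicate (adjusted p from 0.0589 to 0.241), and just missed the threshold without the low count filter (adjusted p = 0.0571) or without the 54 genes seen only in the replicate 1 libraries (adjusted p = 0.0567). Irf3 did not pass, at 30.8 ± 1.62 and 31.5 ± 1.36 CPM. Of 16 negative regulators of interferon signalling, 5 rose, 5 fell and 6 did not pass (also 5 and 5 adjusted over the list alone), with a median of -0.03, a mean of 0.11 and an adjusted p of 0.924. The ISG15 protease gene Usp18 rose from 0.516 ± 0.153 to 3.99 ± 0.889 CPM (log2 fold change 2.97, SE 0.31), and Samhd1 fell 1.25-fold.

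NF-kB and inflammatory target genes moved both ways. Of 39 tested, 15 rose, 10 fell and 14 did not pass (15 and 10 adjusted over the list alone), with a median log2 fold change of 0.20 (0.17 and 0.15 in the replicate 1 and 2 libraries). The median over all tested genes was 0.006. At least 2-fold, 4 members rose and 1 fell. Ier3 rose 1.93-fold, Ptgs2, which encodes cyclooxygenase 2, 1.40-fold, and Nfkbia, the inhibitor of NF-kB, 1.39-fold (log2 fold change 0.48, SE 0.05). The neutrophil chemokine Cxcl1 rose from 20.8 ± 1.70 to 36.1 ± 0.676 CPM, and Nos2 from 0.436 ± 0.215 to 2.00 ± 0.496 CPM. Mmp9 fell from 209 ± 2.30 to 100 ± 1.24 CPM (log2 fold change -1.06, SE 0.03, adjusted p = 4.71e-10) and the macrophage growth factor Csf1 fell by 0.62. Tnfaip3 was 1.07-fold lower in uniSTING (adjusted p = 0.0263), a call and direction lost once a trend with gene length was removed (log2 fold change 0.02) and a call lost with DESeq2 (adjusted p = 0.152) and without Mock replicate 1 or uniSTING replicate 1 (adjusted p = 0.104 and 0.196). Tnf had 5 counts in Mock and 25 in uniSTING, a ratio of 4.50 (1.69 to 15.1), and Il6 had 1 count in all. The list did not pass camera's test (adjusted p = 0.195). Limma's fry, which does not compare a list with other genes, found it higher on balance (adjusted p = 0.0134).

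The interferon-stimulated list moved more than the NF-kB list. Their medians differed by 0.52 on the log2 scale, by 0.65 in the replicate 1 libraries and by 0.52 in the replicate 2 libraries. On the union of both lists, limma's camera placed the difference past the threshold of 0.05 with the preset and with the estimated correlation.

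Chemokines that attract T cells and NK cells were measured by 5 tested genes, of which 4 rose and 1 fell (4 and 1 adjusted over the list alone), and the list did not pass (median 0.69, adjusted p = 0.0715), though it did in edgeR and camera fits without uniSTING replicate 1 or 2 (adjusted p = 0.0394 and 0.0459). With an estimated correlation over all 4 libraries the list had an adjusted p of 0.386. By limma's fry, which does not compare it with other genes, the list was higher on balance (adjusted p = 0.00489). Cxcl10 rose by 2.38 (SE 0.21, adjusted p = 4.02e-06). Cxcl16 rose 1.43-fold and Ccl5 rose from 4.83 ± 0.334 to 7.83 ± 1.08 CPM (adjusted p = 0.00266). Cxcl11 had 2 counts in Mock and 67 in uniSTING, a ratio of 30.2 (8.03 to 254).

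Of 24 tested genes of MHC class I antigen presentation, 11 rose, 2 fell and 11 did not pass (13 and 2 adjusted over the list alone), with a median of 0.19. The class I heavy chain gene H2-K1 rose from 137 ± 1.28 to 183 ± 2.28 CPM (log2 fold change 0.42, SE 0.03), the chaperone gene Calr 1.28-fold and the peptide transporter gene Tap1 1.29-fold (adjusted p = 0.0208). B2m, the class I light chain, rose by 0.25, which became -0.03 once the length trend was removed and a fall by 0.16 that passed (adjusted p = 2.21e-04) once length and GC trends were removed, so that its direction depends on these trends. The list passed camera's test (adjusted p = 0.0181, against adjusted p = 0.386 with an estimated correlation) and lost its call with the length trend removed (median 0.06, adjusted p = 0.170) and without uniSTING replicate 2 (adjusted p = 0.0885). The call of Tap1 was lost with DESeq2 (adjusted p = 0.127) and without Mock replicate 1 or uniSTING replicate 2 (adjusted p = 0.130 and 0.0873). H2 genes are polymorphic and near-identical to each other, and 4T1 carries alleles other than those of the reference strain, so that their levels are uncertain. Among 15 tested checkpoint and co-stimulatory ligands, 7 rose, 2 fell and 6 did not pass (7 and 3 adjusted over the list alone; list adjusted p = 0.402). Cd274, which encodes PD-L1, rose from 1.54 ± 0.253 to 2.48 ± 0.186 CPM (log2 fold change 0.68, SE 0.26, adjusted p = 0.0484), a call lost without any 1 of the 4 libraries (adjusted p from 0.0595 to 0.224) and with DESeq2 (adjusted p = 0.227) or limma-voom (adjusted p = 0.0549). Tnfsf9 rose 1.96-fold. Cd276 and Ulbp1 fell 1.30-fold and 1.32-fold. Cd74 rose among 3 tested MHC class II genes, the others being H2-DMa and H2-Ab1, which did not pass (list adjusted p = 0.418; 1 rose adjusted over the list alone).

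Genes of metabolism rose too. Of 26 tested glycolysis and hypoxia genes, 22 rose, 1 fell and 3 did not pass (22 and 1 adjusted over the list alone), with a median of 0.49. The lactate dehydrogenase gene Ldha rose from 1898 ± 7.47 to 2871 ± 15.3 CPM (log2 fold change 0.60, SE 0.01, adjusted p = 8.18e-11), Pgk1 1.53-fold, and the hypoxia-responsive gene Ndrg1 1.94-fold. Of 23 cholesterol synthesis genes, 19 rose, 3 fell and 1 did not pass (19 and 3 adjusted over the list alone), with a median of 0.48. Mvd rose from 48.8 ± 1.14 to 96.9 ± 0.535 CPM, Idi1 rose 1.81-fold and Msmo1 1.69-fold. Both lists passed camera's test (adjusted p = 4.32e-08 for glycolysis and hypoxia and 2.49e-06 for cholesterol synthesis), but not with an estimated correlation (adjusted p = 0.283 and 0.351). Their medians stayed at 0.50 and 0.50 once the length trend was removed.

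Ribosomal protein genes rose in 44 of 49 cases, with 3 that fell and 2 that did not pass (44 and 4 adjusted over the list alone), and nuclear genes of oxidative phosphorylation in 24 of 32 cases, with none falling and 8 that did not pass (25 and 0 adjusted over the list alone). Rpl37 rose 1.69-fold and Rps24 1.46-fold, and the cytochrome oxidase genes Cox7c and Cox6c rose 1.72-fold and 1.60-fold. Mitochondrially encoded genes went the other way, with 9 of 12 tested lower and none higher (9 adjusted over the list alone). Among them mt-Nd4 fell from 1177 ± 6.12 to 960 ± 21.1 CPM (log2 fold change -0.29, SE 0.02). The medians were 0.31, 0.24 and -0.17, with camera's adjusted p at 2.65e-10, 7.31e-07 and 0.0114 and, with an estimated correlation, adjusted p at 0.351, 0.351 and 0.548. Without uniSTING replicate 2 the mitochondrial list was no longer past the test (adjusted p = 0.0652). These genes are short, and fold changes followed gene length. With the length trend removed the medians were 0.16, 0.12 and -0.41, still past camera's test at adjusted p = 3.69e-05, 0.00723 and 3.12e-05. Ribosomal protein genes have many processed pseudogenes, so their counts of uniquely mapped reads are uncertain.

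Long genes were lower and short genes higher in uniSTING. Over 7992 genes above 16 CPM, log2 fold change and exon length had a Spearman rho of -0.49 across genes, which are not independent replicates. It was -0.49 in the replicate 1 libraries and -0.48 in the replicate 2 libraries, against 0.03 and 0.02 between the libraries of a group. The decile of shortest genes (median 1.24 kb) had a median log2 fold change of 0.27 and the decile of longest genes (median 13.0 kb) one of -0.28. With this trend removed, 5923 genes passed, and 4865 of these were among the 6515, 4763 of them in the same direction.

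**Figure D4:**
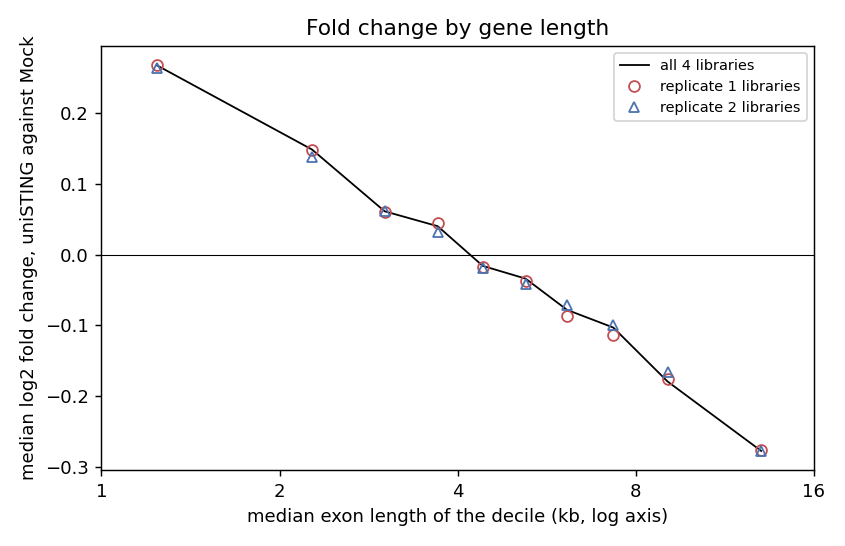
Median log2 fold change of uniSTING against Mock (vertical axis) in 10 bins of genes by exon length (horizontal axis, kb, log scale), for all 4 libraries and for the libraries of each replicate number. It falls from 0.27 at 1.24 kb to -0.28 at 13.0 kb, and both replicate numbers follow the line.

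The 8 genes with the largest falls by the rule for named genes were all replication-dependent histone genes, which supply histones to newly made DNA. Hist1h3e (ENSMUSG00000069273, chromosome 13, 23745708 to 23746543, GRCm39) fell from 5.81 ± 0.285 to 0.554 ± 0.273 CPM (log2 fold change -3.43, SE 0.29, adjusted p = 2.93e-06), and Hist2h2ac from 2.43 ± 0.467 to 0.207 ± 0.00893 CPM. Hist1h1d, a linker histone gene, fell by 2.32. As a group put together after these values were seen, 28 of 37 tested histone cluster genes fell, none rose and 9 did not pass, with a median of -1.86 (-1.77 and -1.63 in the replicate 1 and 2 libraries) and 3468 counts in Mock against 1685 in uniSTING. Histone genes are near-identical copies, so reads can be lost or split among them, and single values are uncertain.

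Genes of the cell cycle lists moved both ways. Among 32 DNA replication and G1/S genes, 12 rose, 11 fell and 9 did not pass (12 and 11 adjusted over the list alone), with a median of 0.03 and no difference from other genes by camera (adjusted p = 0.924). Limma's fry, which does not compare the list with other genes, found it lower on balance (adjusted p = 0.0365), against the sign of the median and of camera's direction. Pole fell 1.51-fold and Uhrf1 1.26-fold, whereas the thymidine kinase gene Tk1 rose 1.18-fold. Among 35 G2/M and mitosis genes, 14 rose, 11 fell and 10 did not pass (14 and 11 adjusted over the list alone), with a median of -0.01 and a mean of -0.02 but a camera direction upward (adjusted p = 0.971) and a fry direction downward (adjusted p = 0.0619). Mki67 fell from 302 ± 3.73 to 158 ± 7.27 CPM and the kinetochore gene Cenpf 1.72-fold, whereas Nuf2 rose 1.42-fold. Mki67 and Cenpf have exon lengths of 10061 and 15433 bases.

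Of 18 tested genes of mesenchymal transition, 13 fell, 1 rose and 4 did not pass (13 and 1 adjusted over the list alone). Fn1 (ENSMUSG00000026193, chromosome 1, 71624679 to 71692359, GRCm39) fell from 1892 ± 2.64 to 835 ± 13.2 CPM (log2 fold change -1.18, SE 0.02, adjusted p = 5.92e-12) and the intermediate filament gene Vim fell 1.16-fold. Of 17 TGF-beta pathway genes, 9 fell, 2 rose and 6 did not pass (9 and 3 adjusted over the list alone). Smad3 and Ltbp1 fell 1.62-fold and 1.57-fold, whereas Id2, an inhibitor of helix-loop-helix factors, rose by 1.23. The medians of -0.28 and -0.20 passed camera's test at adjusted p = 0.00202 and 0.0225, but not with an estimated correlation (adjusted p = 0.351 for each). With the length trend removed, the mesenchymal list still passed (median -0.22, adjusted p = 4.07e-04) and the TGF-beta list did not (median -0.13, adjusted p = 0.0672). Epithelial identity genes went both ways, with 13 of 24 rising and 7 falling (13 and 7 adjusted over the list alone; list adjusted p = 0.224). The keratin gene Krt19 rose from 66.0 ± 1.47 to 132 ± 3.56 CPM, and the tight junction gene Tjp1 fell 1.58-fold.

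Autophagy and lysosome genes rose in 14 of 24 cases and fell in 3 (14 and 3 adjusted over the list alone), with a median of 0.24, an adjusted p of 0.0122 and, with an estimated correlation, an adjusted p of 0.351. The cathepsin gene Ctsl rose 1.35-fold and the autophagy receptor gene Sqstm1 1.18-fold. Apoptosis genes (10 of 28 rose and 4 fell; 10 and 4 adjusted over the list alone) and p53 target genes (6 of 18 rose and 2 fell; 6 and 2 adjusted over the list alone) did not pass as lists (adjusted p = 0.402 and 0.107). The necroptosis effector gene Mlkl rose 1.30-fold and Mdm2 1.40-fold, and Apaf1 fell 1.42-fold. Unfolded protein and integrated stress response genes moved both ways, 16 of 27 up and 9 down (16 and 10 adjusted over the list alone; list adjusted p = 0.418), with Ddit4 up 1.63-fold, the chaperone gene Hspa5 up 1.14-fold and Asns down 1.21-fold. Of 17 immediate early genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone; list adjusted p = 0.764), and Myc fell 1.33-fold.

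**Figure D5:**
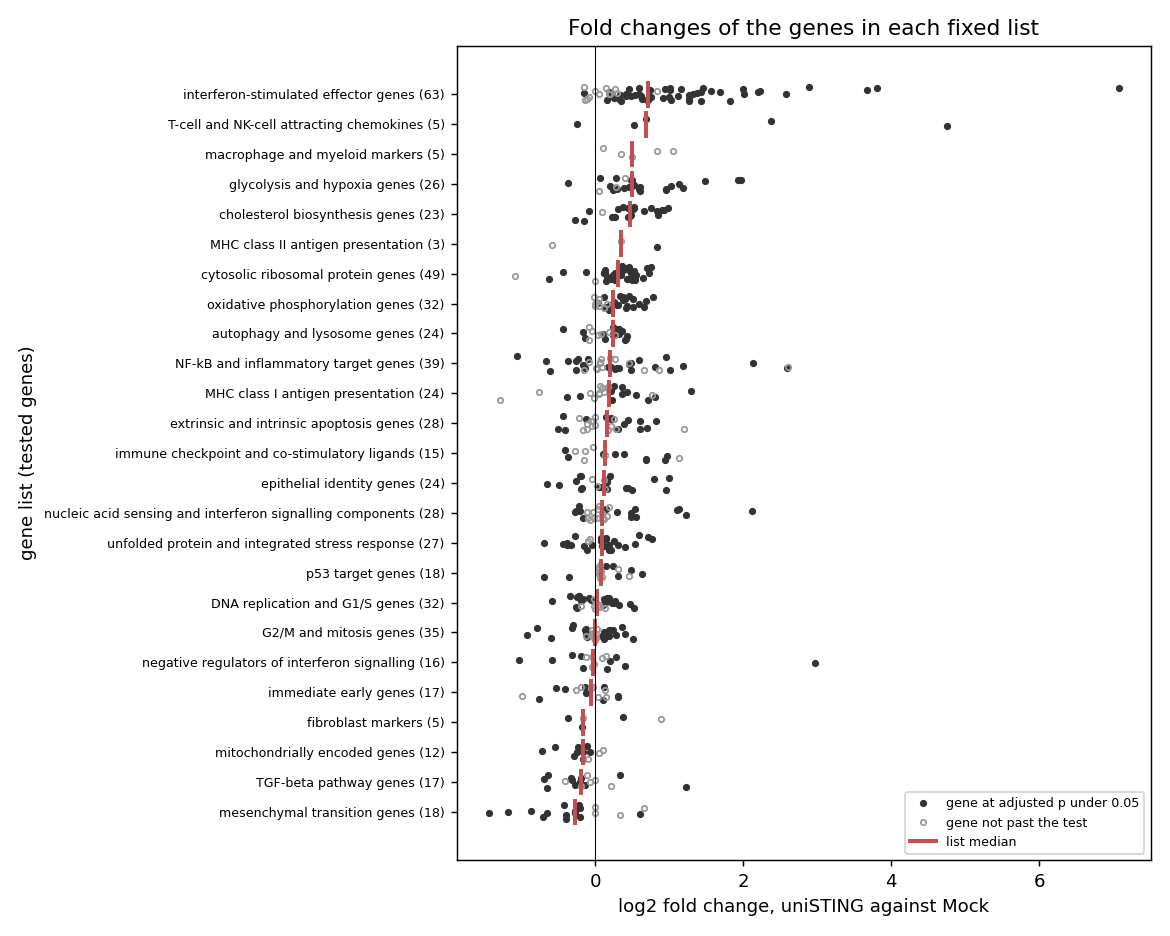
Log2 fold change of uniSTING against Mock (horizontal axis) of each tested gene in the 25 lists with at least 3 tested genes (vertical axis, number of genes in brackets), filled where the adjusted p is under 0.05, with the list median as a red bar. Over the 4 libraries the median was 0.72 for interferon-stimulated effector genes, next to 0.69 for the 5 chemokine genes (0.81 and 0.89 in the replicate 1 libraries), and -0.28 for mesenchymal transition genes.

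Markers of other cell types were mostly absent or untested. Of 21 macrophage and myeloid markers 5 were tested and none passed in the main fit (camera's list adjusted p = 0.703), nor did either of 2 tested lymphocyte markers. Calls that myeloid markers gained with the replicate block or without the low count filter are given below. Lyz2 had 155 and 290 counts in the replicate 1 libraries of Mock and uniSTING and none in the replicate 2 libraries, as S100a9 did (44 and 66 counts), and S100a8 had 37 and 79 counts against 0 and 2. Among 5 tested fibroblast markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.16 against a mean of 0.11 and an adjusted p of 0.793, and Pdgfra rose 1.29-fold, a call lost with DESeq2 (adjusted p = 0.190) and without Mock replicate 2 (adjusted p = 0.163). The only endothelial marker tested, with a log2 fold change of -0.29, fell. In all, 54 genes were seen in the replicate 1 libraries of both groups and nearly or wholly missing from both replicate 2 libraries, 50 of them tested and none past the test, and without them 6743 genes passed.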

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

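The trend removals, the omission of the 54 genes and the use of 1 replicate number alone were chosen after seeing the data. With DESeq2, limma-voom, other size factors or filters and the trend removals, between 4517 and 6755 genes passed, and without 1 library between 5305 and 6098, where the lone library of a group is assumed to vary like the other group. A threshold of 2-fold left 414 genes, 259 higher and 155 lower. The replicate block gave 6777 genes, 6445 of them among the 6515, and 10 lists; Cgas lost its call and Cd14, S100a8 and Lyz2 gained one. Same-numbered libraries deviated together at a Pearson r of 0.53 across 7992 genes, or 0.076 without the 54 genes (Spearman 0.008 with and without them). The numbers were therefore not taken to pair the samples. These correlations cover genes above 16 CPM, and most of the 54 genes lie below that. The 54 genes had 4103 and 6252 counts in the replicate 1 libraries of Mock and uniSTING, against 13 and 14 in the replicate 2 libraries. In these genes the same-numbered libraries did have a feature in common, whose source is not known. The interferon-stimulated list kept its call in all settings except the estimated correlation. There its median of 0.716 had an adjusted p of 0.283 (limma's camera) and 0 lists passed. In the self-test a truly shifted list was missed with an estimated correlation too. The self-test's genes were independent, so that miss does not show that the preset correlation is adequate. The NF-kB list's median was 0.166 and 0.146 in replicates 1 and 2 alone, and the difference of the 2 lists 0.646 in replicate 1 alone; in these the only change is fewer samples.

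Among 143 other list and gene values, 6 lost their call with DESeq2, 1 with limma-voom and 0 with other size factors. With no low count filter the fibroblast median was 0.344, where more genes were tested. In that setting Cd14, S100a8 and Lyz2 gained a call (edgeR, adjusted p = 0.0310, 0.00617 and 3.33e-06), although all counts of Lyz2 lay in the replicate 1 libraries. With the length trend removed, the medians of the G1/S and G2/M lists were -0.004 and 0.036, and Irf3, Tnfaip3 and B2m had log2 fold changes of 0, 0.02 and -0.03. With length and GC trends removed, the fibroblast median was 0.056 and Tnfaip3 and B2m had 0 and -0.16, the latter past the test; the cause was not tested beyond the trends removed. Leaving out 1 library gave medians from -0.093 to 0.095 for negative regulators of interferon signalling, -0.025 to 0.998 for MHC class II, -0.011 to 0.191 for apoptosis, -0.002 to 0.029 for G1/S, -0.028 to 0.008 for G2/M, -3.54 to 6.393 for myeloid markers and -0.342 to 0.443 for fibroblast markers. Irf3 ranged from -0.02 to 0.09, S100a8 from -3.54 to 8.51, Lyz2 from -9.52 to 10.36, S100a9 from -7.69 to 8.22 and Col1a2 from -0.64 to 2.56, the myeloid genes lowest without uniSTING replicate 1 and highest without Mock replicate 1, since only the replicate 1 libraries held counts of Lyz2 and S100a9 and all but 2 of those of S100a8. Depth limits the genes under about 10 counts, such as the interferon genes.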

Other observations

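The tests of the length trend as the cause of the list changes, of length-dependent recovery, of S phase and of repeat sequencing were chosen after the results were seen. Genes in this part were singled out after their values were seen, unless the report names them. The nuclear non-coding RNA Neat1 rose by 0.59 on the log2 scale and Malat1, its neighbour, fell by 0.20. Variant histone genes expressed outside S phase did not fall with the cluster genes, with H2afz at 0.27 and H3f3a at 0.24, both higher, and H3f3b at -0.03, which did not pass. In the list of glycolysis and hypoxia genes, the largest rises were those of the hypoxia-responsive genes Ankrd37 (1.97), Adm (1.93) and Bnip3 (1.48), while the hexokinase gene Hk2 was the only member to fall, by 0.37.

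The fall of replication-dependent histone genes cannot come from the length trend, since these genes are short (median 0.62 kb) and their median moved from -1.86 to -2.18 once it was removed. A candidate explanation is a loss, in the uniSTING libraries, of RNAs without a poly(A) tail as a class, since these histone mRNAs lack one. Small non-coding RNA genes had a median of 0.824, above the bound of -0.5 set beforehand against this, but that bound was judged unfit after the value was seen, because most of the 13 tested genes are small nucleolar RNA genes (median length 81 bases), many of which lie in introns of longer transcripts whose reads they can collect. Fewer cells in S phase may also lower histone mRNA, and the G1/S list, with a median of 0.025 over members going both ways and a fall on balance by limma's fry (adjusted p = 0.0365) but not by camera, does not decide. Both stay open, and the kit's selection step is not given in the sources used here.

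The length trend of fold changes was not carried by ribosomal protein and respiratory chain genes, since rho was still -0.473 over 7713 genes outside them. It was not the whole cause of the rise of interferon-stimulated genes, whose median stayed at 0.566 and past the test after its removal, nor of ribosomal protein genes, whose median went from 0.309 to 0.161 and was still past the test. Both tests are at the preset correlation, and before the removal neither list passed with an estimated one (limma's camera, adjusted p = 0.283 and 0.351). A difference in RNA integrity or size selection between the libraries of the 2 groups may underlie the trend. Within groups the largest absolute rho was 0.026, but the libraries of a group may not be independent, so a technical trend cannot be told apart from an effect of uniSTING on long transcripts.

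The likeness of the libraries of a group was of a size that repeat sequencing of 1 library or 1 RNA sample per group could give. The added coefficient of variation of genes over 10000 counts was at most 0.998% (variance 1.80 and 1.78 times counting noise, against 1.06 in simulated repeat runs and 91.9 in simulated libraries that vary by 10%). The simulated repeat runs hold counting noise only, and both groups lie above them. For genes with at least 50 and under 200 counts, the added coefficient of variation was 7.98% in Mock and 11.9% in uniSTING. Per the file headers, the alignments carry 1 code per group and a second code that follows the replicate number, and separate cultures with a very low spread stay open, while repeat runs of 1 library would leave the replicate 1 transcripts below without a source unless they entered at a later step. The 54 genes of the replicate 1 libraries (4103 counts in Mock and 6252 in uniSTING, against 13 and 14 in replicate 2) include Ins2 (1226 and 2117 counts), Ins1, Gcg and the surfactant gene Sftpc, and hold 15 of 20 pancreatic islet, 10 of 15 lung epithelium, 2 of 5 red blood cell and 0 of 12 exocrine pancreas markers, lists written after these genes were seen. RNA or reads of other mouse samples in the replicate 1 libraries may be their source, and the 10 islet and lung markers outside the 54 genes had 402 counts in replicate 1 and 396 in replicate 2, a ratio per library size of 1.316 (1.14 to 1.52), between the bounds set beforehand. Foxj1, Mafa and Lamp3, with at least 10 counts in every library, had 308 against 388 counts and the other 7 had 94 against 8. That split itself gathers markers low in replicate 2, and the 10 markers are by construction those less confined to replicate 1. The ratio therefore does not decide. Expression by 4T1 cells in 1 of 2 preparations was not tested directly. It would have to raise islet, lung and red blood cell markers together in Mock and uniSTING alike. Other genes differed little between the libraries of a group. For the 54 genes, these values argue against expression by 4T1 cells.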
